A study of Arabidopsis thaliana with 30 samples.

How the data were processed

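Total RNA of Arabidopsis thaliana seedlings was measured on 30 one-colour Agilent arrays labelled with Cy3. Per the labels, seedlings were 7 days old, had grown in 16 h light and 8 h dark, and were harvested at 2 times, ZT1 (1 h after lights on) and ZT16 (16 h after lights on). The 5 genotypes were wild type (Col), the GI-null mutant gi-2, and gi-2 carrying the GI promoter in front of GI fused to GFP (called GI), of the same fusion with a nuclear localisation signal (GI-NLS) or of the same fusion with a nuclear export signal (GI-NES). Each of the 10 groups held 3 arrays, which the series' design text calls biological replicates. The labels describe the Col and gi-2 arrays as analyses of samples deposited earlier. Nothing in the labels says how separate the cultures of the replicates were, so p-values measure the spread between these arrays, part of which may be technical. Within groups, arrays correlated across probes at Pearson r of at most 0.991, so no array's values were a copy of another's in its group. This does not exclude that 1 RNA was measured on more than 1 array.

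The authors deposited 1 scanner file per array with spot intensity values made by Agilent Feature Extraction 10.7.1.1, per the file headers. The processed intensity had the background subtracted and the spatial trend removed, per the file headers, and was not normalized between arrays. The authors also deposited a value table of the series in log2 units. Its making is not given in the sources used here. Set against the scanner files, its columns correlated with the log2 median spot signal at Pearson r between 0.991 and 1.00 across spots, so its scale is log2 and its direction is that of the signal. Its column medians were 7.61 at ZT1 and lay between 7.71 and 7.72 at ZT16, and the columns of one time had nearly one distribution. Whether it was centred in any other way stays unknown. Whether both times were normalized together is not given, so it was used only as an alternative for comparisons within a time.

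Each array held 62976 spots, of which 61657 were not controls and represented 43603 probes, 25549 with 1 spot and 18054 with 2 spots. The share of non-control spots well above background ranged from 61.8% to 73.4% between arrays. The 75th percentile of the processed signal ranged from 447 to 1429 and the median background from 23 to 45. At most 1 spot was saturated on an array and at most 53 were marked as outliers. The number of arrays, rather than a count of molecules, limits the precision.

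Control spots and outlier spots were left out. The log2 processed signal minus the array's 75th percentile of it was averaged over the spots of a probe. A probe was tested where it was well above background on all 3 arrays of at least 1 group and had no missing value, which left 29950 probes. A missing value removed 95 probes, and 13558 were not well above background on all 3 arrays of any group. All levels below are on this log2 scale, relative to the array's own 75th percentile, and one probe's level is not set against another's. A probe that was not well above background on any array of a group has only a bound there. The fold is then written as "at least", from the brighter group's mean to the dimmer group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

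Group means were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 30 arrays, with 20 residual and 2.85 prior degrees of freedom. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called, in each comparison separately. Every adjusted p printed comes from limma, is two-sided, and is adjusted over the 29950 probes. Numbers of probes at an unadjusted p under 0.05 are also given. With no difference, about a share of 0.05 of the tested probes would fall there. A number below that share is no sign of missed changes. Random blocks used duplicateCorrelation with statmod 1.5.0. Tables were read with the data.table package (version 1.17.8) and plots were drawn with matplotlib 3.10.9. The comparisons, the tests, the arrays in each fit and most alternatives were fixed before the data were examined. Those added later were the scan day as a random or a fixed block, the array's signal strength as a covariate, and the replicate block without 1 array that lay with the other time. The alternatives fixed in advance were background correction by normexp with an offset of 50, quantile normalization, no filter on dim probes, a fit of only the groups compared, replicate number as a block, slide as a random block over all arrays, slide as a fixed block in a fit that left out the genotypes on other slides, the deposited value table, a 2-fold minimum, and each array left out in turn. The scanner files hold no mean spot signal, for which normexp was planned. It was run on the median spot signal instead, and this version counts among the alternatives added later.

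The arrays lay on 8 slides scanned on 6 days. Col and gi-2 shared slide 2 (day 2), slide 1 (day 1) and slide 6 (day 4) for replicates 1, 2 and 3. GI and GI-NLS shared slide 3 and slide 4 (both day 3) and slide 7 (day 5). GI-NES replicates 1 and 2 were on slide 5 (day 4) and replicate 3 on slide 8 (day 6). Every slide held both times. Col and gi-2 share no slide or day with GI and GI-NLS, nor does GI-NES with the latter, so for those comparisons slide and day entered only as random blocks. A random block cannot separate slide or day from genotype there, so those comparisons stay confounded with both. GI-NES shared day 4 but no slide with Col and gi-2. Overlaps built on such comparisons carry the same limit. For values within a slide, the lone array of a group was assumed to vary like the other groups.

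Replicate numbers come from the labels. They were taken to pair the arrays of a comparison where the deviations from the group means correlated above 0.1 in every pair of same-numbered arrays. This held in 16 of the 23 comparisons. It failed for GI-NES against gi-2 at both times, GI-NLS against GI at ZT16, GI-NES against GI at ZT1, GI-NLS against GI-NES at ZT16 and both differences of time effects. The median pair correlation within the paired comparisons ranged from 0.189 (GI-NLS against gi-2 at ZT1) to 0.599 (ZT16 against ZT1 in GI). Even in paired comparisons, the main counts and their adjusted p come from the fit without the replicate number. Counts that the replicate block moved by more than 1.5 times are also given.

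A time score placed each array between ZT1 and ZT16. It was computed on probes called in the same direction between the times in every genotype other than the array's own and gi-2, with 0 at the ZT1 mean and 1 at the ZT16 mean of those genotypes. For gi-2 arrays these were 915 probes higher at ZT16 and 887 higher at ZT1. The score was devised after the arrays had been compared. Overlaps between comparisons that share arrays were set beside the number given by independent lists and beside 100 simulations. Each simulation left every group unchanged, gi-2 included, and shuffled the deviations of all 30 arrays over the groups. It kept neither the real gi-2 arrays nor the replicate numbers. With no change placed, few probes are called, so a low simulated overlap follows by construction. The fit was tested on simulated data: of changes placed into the gi-2 against Col comparison at ZT16 over 29950 probes, 8.96% were recovered at 1.5-fold, 47.8% at 2-fold and 92.4% at 4-fold.

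The arrays are identified here by probe IDs alone, and the reference used here lists genes by locus and symbol, which the files do not pair with probes. No gene is named for this reason. The 19 gene lists fixed in advance, the levels of clock and flowering genes, and the check of the targeted gene in the mutant were not run. All counts are of probes, not genes, and several probes may report 1 gene. The rule for named probes was reduced to at most 2 IDs that were higher and 2 that were lower in each main comparison (gi-2 against Col, GI against gi-2 and GI-NLS against GI-NES at each time, and ZT16 against ZT1 in Col). These were those with the largest called change and no overlap between the arrays of both groups, and their values are also given for the other comparisons.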

Results

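The data were 30 one-colour arrays of 7-day-old Arabidopsis seedlings, with 3 arrays for each of 5 genotypes at ZT1 (morning) and ZT16 (evening). GI (GIGANTEA) is a plant protein with known roles in the circadian clock and in flowering time. The series' title asks what GI does in the nucleus and in the cytosol. To this end the mutant gi-2 was compared with wild type (Col), and with lines in which GI was put back without a targeting signal (GI), with a nuclear localisation signal (GI-NLS) or with a nuclear export signal (GI-NES). Between 61.8% and 73.4% of spots were well above background on an array, and 29950 probes were tested. Of 125 calls of named probes, normexp ended 38 and a fit of only the groups compared 50, and no alternative reversed one. Several alternatives leave the log2 difference unchanged by construction and so could not reverse a call.

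Far more probes differed between the harvest times than between genotypes. In Col, 4435 probes differed between the times, 2304 higher and 2131 lower at ZT16, and 2086 of them changed at least 2-fold. Among the largest rises was A_84_P297344, not well above background on any Col array at ZT1 and at 0.86 ± 0.27 (SD, n = 3) at ZT16, at least 99.5-fold higher (limma, adjusted p = 7.14e-05). A_84_P812905 rose from -5.24 ± 2.71 to 2.58 ± 2.06 (adjusted p = 0.00984), a call that ended without Col ZT1 replicate 1 or Col ZT16 replicate 2 (adjusted p = 0.0783 and 0.0568). A_84_P519046 was at 1.05 ± 0.64 at ZT1 and not well above background at ZT16, at least 76.3-fold lower (adjusted p = 8.46e-06). A_84_P279060 was at 2.34 ± 0.02 at ZT1 and at least 185-fold lower at ZT16 (adjusted p = 2.98e-06). With the replicate number as a block, 7404 probes were called. With slide as a fixed block, a fit that also left out the genotypes on other slides, 7084 were, and with slide as a random block over all arrays 7464. Within slides 1, 2 and 6, 287, 466 and 619 probes passed. Without the array Col ZT1 replicate 1, 2777 did.

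Each line carrying GI also had many time effects. Between ZT1 and ZT16, 3621 probes changed in GI (1885 higher, 1736 lower), 3071 in GI-NLS (1626 higher, 1445 lower) and 3040 in GI-NES (1471 higher, 1569 lower). The same 4 probes changed in each line in the direction seen in Col. A_84_P297344 was at least 31.9-fold higher at ZT16 in GI, at least 102-fold higher in GI-NLS, and 92.7-fold higher in GI-NES, where 1 of 3 ZT1 arrays was well above background. A_84_P519046 was not well above background at ZT16 in any of these lines, at least 76.5-fold lower in GI, 42.4-fold in GI-NLS and 43.2-fold in GI-NES. The call of A_84_P812905 ended without ZT1 replicate 1, ZT16 replicate 2 or ZT16 replicate 3 in GI (adjusted p = 0.0883, 0.0732 and 0.0583) and in GI-NLS (adjusted p = 0.0994, 0.103 and 0.0585). The replicate block gave 6165, 5474 and 5615 probes, the fixed slide block without the other genotypes 4531, 3859 and 2700, and the random slide block 6065, 5509 and 5401. Within single slides, GI had 543, 89 and 408 probes (slides 3, 4 and 7), GI-NLS 49, 66 and 17 on those slides, and GI-NES 1365 on slide 5 and 177 on slide 8. With only the GI arrays in the fit, 1058 probes passed in GI. GI-NLS had 1793, 1961 and 1739 probes without ZT1 replicate 1, ZT1 replicate 3 and ZT16 replicate 2, and GI-NES had 1920 and 1961 without ZT1 replicate 1 and ZT16 replicate 3. No probe differed in its time effect between GI-NLS and GI-NES by limma (0 called, 149 at an unadjusted p under 0.05, 440 with the replicate block).

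In gi-2 only 2 probes differed between the times, 1 higher and 1 lower, and 1 array decided this count. The array labelled gi-2 ZT1 replicate 3 had a time score of 0.897. The 15 ZT16 arrays lay between 0.887 and 1.06 and the other 14 ZT1 arrays between -0.145 and 0.141, including the other gi-2 ZT1 arrays at 0.0305 and 0.139. Of all arrays, it correlated best across probes with gi-2 ZT16 replicate 3 (Pearson r = 0.992, probes not being independent). No pair of arrays within a labelled group correlated above 0.991. Without it, 2418 probes differed between the times in gi-2, 1317 higher and 1101 lower at ZT16, the 2 above among them. With all arrays and the replicate block, 753 did, with slide as a random block 751, with the fixed slide block without the other genotypes 0 (4692 at an unadjusted p under 0.05), and within slides 1, 2 and 6, 0, 2 and 8. Because of this array, the main counts that use gi-2 at ZT1 are also given without it, a choice made after the data were seen. The array also enters the shared estimate of the spread used for all other comparisons. For A_84_P279060, for example, the SD at ZT1 was 3.56 in gi-2 and 0.02 in Col. The other comparisons were not refitted without this array alone, so what it does to their counts is not known.

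**Figure D1:**
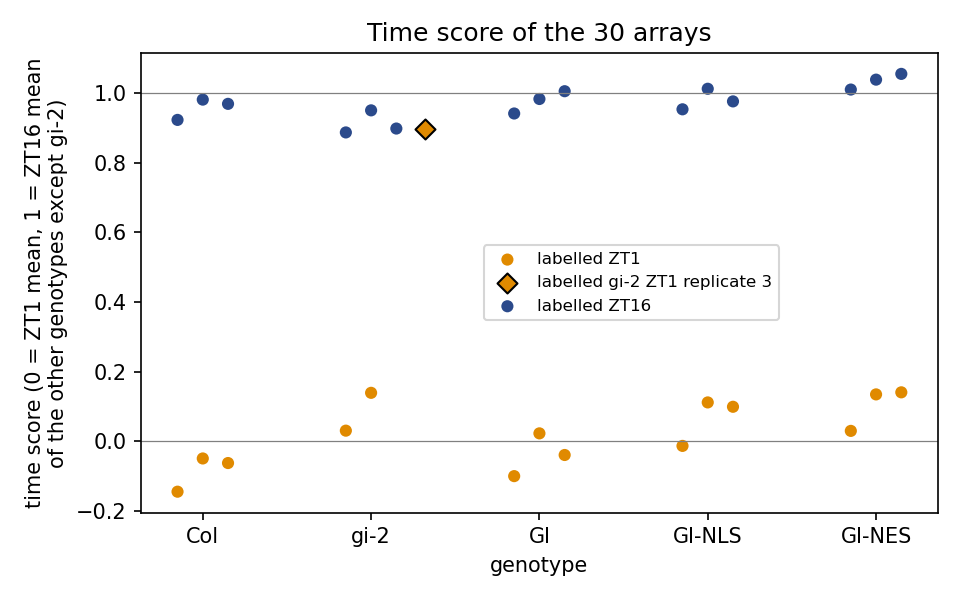
Time score of each of the 30 arrays (vertical axis, no unit, 0 at the ZT1 mean and 1 at the ZT16 mean of the other genotypes except gi-2) by genotype and labelled harvest time, 1 symbol per array, spread sideways to keep symbols apart. The diamond is the array labelled gi-2 ZT1 replicate 3, at 0.897 among the ZT16 arrays, while all other ZT1 arrays lie between -0.145 and 0.141.

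At ZT16, gi-2 and Col differed in a small set of probes, some of them by more than 10-fold. Of 73 probes that differed between gi-2 and Col, 42 were higher and 31 lower in gi-2. A_84_P17055 was at -1.02 ± 0.38 (SD, n = 3) in Col and not well above background in gi-2, at least 21.7-fold lower (adjusted p = 2.03e-05), and A_84_P784337 was at least 18.1-fold lower (adjusted p = 3.95e-05). In Col both were higher at ZT16 than at ZT1, by 4.51 and 4.76 log2 units. In the other direction, A_84_P18763 was at -3.39 ± 0.82 in gi-2 and not well above background in Col, at least 3.50-fold higher (adjusted p = 5.46e-04, and 0.0545 with normexp). In Col it was at -1.73 ± 0.26 at ZT1 and at least 11.1-fold lower at ZT16. A_84_P22244 was 10.1-fold higher in gi-2, at -0.18 ± 0.35 against -3.53 ± 0.62 (adjusted p = 2.03e-05).

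Within slides 1, 2 and 6, 7, 31 and 13 probes passed. The replicate block gave 125 probes and slide as a random block 122, but slide as a fixed block without the other genotypes 38 and a fit of only these groups 31, and the deposited table split its calls as 59 higher and 24 lower. The count fell to 43, 46, 46, 36 and 48 without Col replicates 1 and 2 and gi-2 replicates 1, 2 and 3 of ZT16.

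At ZT1, 109 probes differed between gi-2 and Col, 78 higher and 31 lower in gi-2. Without the array labelled gi-2 ZT1 replicate 3, 41 did, 23 higher and 18 lower, of which 38 were among the 109. A_84_P587219 was 17.8-fold lower in gi-2, at -5.58 ± 0.37 (well above background on 1 of 3 arrays) against -1.43 ± 0.48 in Col (adjusted p = 1.55e-07). At ZT16 it was at least 10.3-fold lower. A_84_P266650 was 13.0-fold lower in gi-2 (adjusted p = 0.00203, and 0.0677 with slide as a fixed block without the other genotypes). Its gi-2 mean depended on the doubtful array. Between GI and gi-2 at ZT1 its log2 difference was 2.86, and 2.37 without the array labelled gi-2 ZT1 replicate 3 (limma, adjusted p = 0.387). A_84_P22244 was 8.32-fold higher (adjusted p = 1.40e-04) and A_84_P550153, at -3.62 ± 0.37 in gi-2 and not well above background in Col, at least 4.46-fold higher (adjusted p = 1.32e-04, but 0.179 with normexp and 0.0535 from the deposited table). Across the times, 15 probes were called in the same direction, and 9 when the array was left out.

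The ZT1 count rested on few arrays. It was 376 with the replicate block, 104 with that block and without the array, 518 with slide and 278 with scan day as a random block, 21 with slide as a fixed block without the other genotypes, 3 with only these groups in the fit, which ended the calls of A_84_P22244, A_84_P266650 and A_84_P550153, and 20 (6 higher, 14 lower) from the deposited table. Within slides 1, 2 and 6 it was 2, 4 and 928, the last slide holding the doubtful array. Without Col ZT1 replicates 1, 2 and 3 in turn it was 66, 39 and 41, and without gi-2 replicates 1 and 2 it was 469 and 378.

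The difference between the times itself was not equal in gi-2 and Col for 42 probes, 37 with a higher and 5 with a lower ZT16 minus ZT1 value in gi-2. A_84_P18763 is an example: it was at least 11.1-fold lower at ZT16 than at ZT1 in Col, while in gi-2 it was at -3.10 ± 1.15 at ZT1 and -3.39 ± 0.82 at ZT16. Its call ended with slide as a fixed block without the other genotypes (adjusted p = 0.109) and with only these groups in the fit (adjusted p = 0.0689). Without the array labelled gi-2 ZT1 replicate 3, 33 probes differed, 27 higher and 6 lower, and 28 were shared. Slide as a fixed block without the other genotypes left 2 probes and only these groups in the fit 4, while slide as a random block gave 99. Within slides 1, 2 and 6 the count was 0, 0 and 282, and it was 20, 19, 15 and 24 without Col ZT1 replicates 1 and 3 and Col ZT16 replicates 1 and 2, and 65, 22 and 18 without gi-2 ZT1 replicate 1 and gi-2 ZT16 replicates 2 and 3.

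Against gi-2, 62 probes differed in GI at ZT16, 34 higher and 28 lower, and 45 of the 73 probes changed in gi-2 were among them, in the opposite direction. A_84_P17055 and A_84_P784337 were at least 14.7-fold and 11.5-fold higher in GI (adjusted p = 8.46e-05 and 2.02e-04), and A_84_P18763 at least 3.88-fold lower (adjusted p = 4.53e-04, but 0.546 with normexp). A_84_P172991, at -1.93 ± 0.40 in gi-2, was at least 10.4-fold lower in GI (adjusted p = 4.73e-07). A_84_P66154 was 25.1-fold lower in GI (adjusted p = 5.07e-07), at -5.93 ± 0.84 with 1 of 3 arrays well above background, although gi-2 and Col were at -1.28 ± 0.38 and -0.82 ± 0.05. The replicate block called 1.1e+02 probes (rounded) and slide as a random block 52, and a fit of only these groups called 0 (996 at an unadjusted p under 0.05). Without gi-2 ZT16 replicates 2 and 3, 40 and 37 passed. The deposited table also called 62, but split them as 26 higher and 36 lower.

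At ZT1, 48 probes differed between GI and gi-2, 25 higher and 23 lower, and 16 without the array labelled gi-2 ZT1 replicate 3. A_84_P587219 was 19.6-fold higher in GI (adjusted p = 7.89e-08) and A_84_P761415 22.5-fold, at 1.44 ± 0.27 against -3.05 ± 0.29 (adjusted p = 6.69e-07). A_84_P172991 was at least 9.62-fold lower (adjusted p = 1.29e-05, but 0.0873 with normexp and 0.0543 with only these groups) and A_84_P66154 10.1-fold lower (adjusted p = 1.67e-04, but 0.239 with only these groups). Of the 109 probes changed in gi-2, 27 went the other way, or 10 of 41 without the array. Both comparisons use the gi-2 arrays, and 27 stands beside 0.0858 for independent lists and 0 simulated (covariance of the fold changes -0.0611, simulated -0.0567), so part of the excess may come from the shared arrays. The count was 341 with the replicate block, 66 with it and without the array, 28 with slide and 23 with scan day as a random block, 3 with only these groups and 9 (6 higher, 3 lower) from the deposited table. It was 328, 124, 15 and 18 without gi-2 replicates 1 and 2 and GI replicates 1 and 3.

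GI differed from Col in 6 probes at ZT1 (2 higher, 4 lower) and 7 at ZT16 (2 higher, 5 lower), with 2982 and 1311 at an unadjusted p under 0.05 (limma). Normexp called 3 and 4. Quantile normalization called 10 (5 higher, 5 lower) and 9 (4 higher, 5 lower). The deposited table called 6 (3 higher, 3 lower) and 14 (9 higher, 5 lower), so neither the count nor the main direction was steady. A_84_P22244, at -0.66 ± 0.32 and -0.40 ± 0.44 in GI, was 6.29-fold above Col at ZT1 (adjusted p = 0.00256) and 8.75-fold at ZT16 (adjusted p = 1.63e-04). A_84_P66154 was 9.12-fold and 34.4-fold below Col (adjusted p = 0.00123 and 2.03e-07). The replicate block gave 22 and 13 probes, a fit of only these groups 1 and 0 (568 at an unadjusted p under 0.05 at ZT16) and ended both named calls, and 10 were called at ZT1 without GI replicate 2.

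In the lines GI-NLS and GI-NES, part of the probes changed in the mutant at ZT16 differed from gi-2 in the opposite direction. Against gi-2 at ZT16, 39 probes differed in GI-NLS (21 higher, 18 lower) and 129 in GI-NES (88 higher, 41 lower). A_84_P587219 was at least 13.4-fold higher in GI-NLS and at least 13.1-fold higher in GI-NES (adjusted p = 3.89e-08 and 2.23e-08), at -1.72 ± 0.29 and -1.75 ± 0.22 beside -2.10 ± 0.49 in Col. A_84_P17055 was at least 29.6-fold higher in GI-NLS and at least 4.58-fold in GI-NES (adjusted p = 1.19e-05 and 0.00653), and A_84_P18763 at least 4.55-fold and 4.21-fold lower (adjusted p = 0.00156 and 3.41e-04). Normexp ended the calls of A_84_P18763 in both lines and of A_84_P17055 in GI-NES, and scan day as a fixed block that of A_84_P18763 in GI-NES (adjusted p = 0.0605). A fit of only these groups ended the calls of A_84_P18763 in both lines (adjusted p = 0.0781 and 0.121). Of the 73 probes changed in gi-2, 31 went the other way in GI-NLS, 39 in GI-NES, 28 in both and 26 in all 3 lines, and 21 in none. The last were not tested as unrestored.

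These overlaps share the gi-2 arrays. The lines also lay on other slides than Col and gi-2, so slide and line cannot be told apart. Independent lists would share 0.0745, 0.0470 and 0.149 probes with the gi-2 change for GI, GI-NLS and GI-NES, where 45, 31 and 39 were observed. Simulations in which every group was unchanged shared 0, 0 and 4.36 on average, the last from 1 of 100 draws. With no change placed, few probes are called, so these counts cannot show what the shared gi-2 arrays add. The covariance of the fold changes was -0.0383, -0.0787 and -0.0382, beside -0.0580, -0.0557 and -0.0620 in the simulation. Only the GI-NLS value lay further from 0 than its simulated value. The simulation pools the spread of all groups, the gi-2 ZT1 group with the doubtful array included, and ignores the replicate numbers. It therefore does not give what the gi-2 ZT16 arrays alone would add, and the covariances decide nothing. GI-NLS and GI-NES shared 32 probes in the same direction (0.0863 for independent lists, 0 simulated; covariance 0.0732, simulated 0.0584). The 3 gi-2 arrays cannot be split into parts of at least 2, and part of the excess may come from the shared arrays. Without gi-2 ZT16 replicate 2 the overlaps of GI, GI-NLS and GI-NES with the gi-2 change were 26, 14 and 18. A fit of only the groups compared gave 0, 12 and 15. Quantile normalization gave 49, 29 and 40, and the replicate block 64 and 46 for GI and GI-NLS.

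The GI-NLS count was 71 with the replicate block, 14 with only these groups in the fit and 20 without gi-2 ZT16 replicate 2. The GI-NES count was 47 with slide as a random block, 56 with scan day as a fixed block, 20 within day 4, 24 with only these groups, and 84 (44 higher, 40 lower) from the deposited table. Without gi-2 ZT16 replicates 1, 2 and 3 it was 68, 49 and 40, and without GI-NES replicates 1, 2 and 3 it was 47, 198 and 34.

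**Figure D2:**
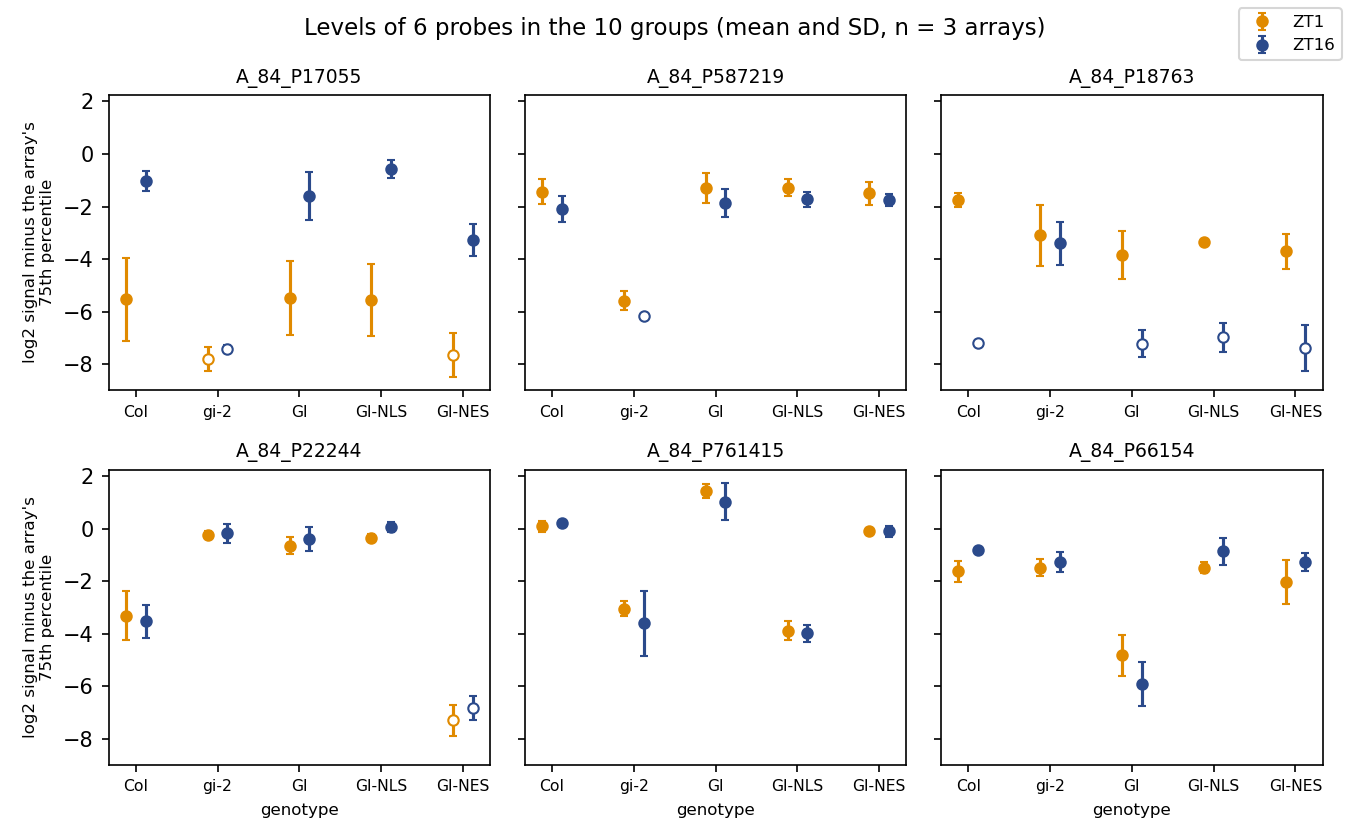
Levels of 6 probes in the 5 genotypes (horizontal) at ZT1 and ZT16, as log2 signal minus the array's 75th percentile (vertical; mean and SD, n = 3 arrays; open symbols mark groups with none of the 3 arrays well above background). A_84_P17055 and A_84_P587219 are low in gi-2 at ZT16 and higher in all 3 lines, A_84_P18763 is high in gi-2 alone at ZT16, A_84_P22244 is lowest in GI-NES, A_84_P761415 is low in gi-2 and GI-NLS, and A_84_P66154 is low in GI.

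At ZT1, 8 probes differed between GI-NLS and gi-2 (5 higher, 3 lower) and 16 between GI-NES and gi-2 (9 higher, 7 lower). A_84_P587219 was 19.7-fold higher in GI-NLS and 16.9-fold in GI-NES (adjusted p = 7.47e-08 and 1.08e-07), and A_84_P172991 was lower, with log2 differences of -3.84 and -4.12 (adjusted p = 8.90e-06 and 2.33e-06), although only 1 of 3 arrays of each line was well above background. Without the array labelled gi-2 ZT1 replicate 3 the counts were 7 and 17. Of the 109 probes changed in gi-2, 6 and 9 went the other way, or 4 and 7 of 41 without the array (0.0130 and 0.0275 for independent lists, 0 and 0.01 simulated with all arrays). The covariance of the fold changes was -0.0879 for GI-NLS (simulated -0.0673) and -0.0494 for GI-NES (simulated -0.0576), the latter closer to 0 than its simulated value. Here too the simulation pools the spread of all groups and ignores the replicate numbers, so these values decide nothing. With the replicate block GI-NLS had 22 probes, 12 without the array, and it had 55 without gi-2 ZT1 replicate 1. GI-NES had 160 probes with scan day as a fixed block and 1069 within day 4, whose only gi-2 ZT1 array is the doubtful one, and each line had 3 with only its groups in the fit, which ended the call of A_84_P172991 in GI-NES (adjusted p = 0.112).

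Between nuclear and untargeted GI, 6 probes were called at each time (4 higher, 2 lower in GI-NLS). Of 29950 probes, 2861 at ZT1 and 690 at ZT16 had an unadjusted p under 0.05 (limma), and 6908 at ZT1 with the replicate block. With no difference, about 0.05 of the probes would fall there, and the ZT16 number lay below that share. In simulated data, 50.7% (ZT1) and 52.2% (ZT16) of 2-fold changes placed into this comparison were recovered. The small number of calls therefore does not show that the lines were alike. A_84_P761415 was 39.8-fold lower in GI-NLS at ZT1 and 32.2-fold at ZT16 (adjusted p = 6.90e-08 and 1.26e-07), at -3.99 ± 0.33 at ZT16, where gi-2 was at -3.60 ± 1.24. A_84_P66154 was 10.0-fold and 33.3-fold higher in GI-NLS (adjusted p = 2.99e-04 and 1.61e-07). These genotypes shared slides 3, 4 and 7, within which 7, 3 and 7 probes passed at ZT1 and 138, 8 and 10 at ZT16. Slide as a random block gave 11 and 9 probes, slide as a fixed block without the other genotypes 3 and 2, and a fit of only these groups 2 and 0 (293 at an unadjusted p under 0.05 at ZT16), the last ending the calls of A_84_P66154 at both times and of A_84_P761415 at ZT16. The replicate block called 39 at ZT1, and 10 were called without GI ZT1 replicate 2.

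Cytosolic GI differed from untargeted GI in 11 probes at ZT1 (6 higher, 5 lower in GI-NES) and 16 at ZT16 (8 higher, 8 lower). A_84_P22244 was not well above background in GI-NES and at least 32.0-fold lower at ZT1 and 33.6-fold at ZT16 (adjusted p = 2.32e-10 and 4.44e-10). A_84_P762010 was 14.7-fold and 16.3-fold higher in GI-NES (adjusted p = 6.40e-04 and 1.96e-04). A_84_P66154 was 6.86-fold and 25.3-fold higher (adjusted p = 0.00253 and 8.05e-07), the ZT1 call ending with normexp (adjusted p = 0.145) and without GI-NES ZT1 replicate 2 (adjusted p = 0.0507). A fit of only these groups called 2 and 1 probes and ended the calls of A_84_P762010 and A_84_P66154 at both times. The ZT16 count was 10, 45 and 9 without GI-NES replicates 1, 2 and 3.

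Nuclear and cytosolic GI differed directly in 6 probes at each time, 4 higher and 2 lower in GI-NLS. The labels give no second line of any construct, so here and in the other comparisons of these lines the place of GI and the line itself cannot be told apart. A_84_P22244 was at -0.35 ± 0.13 in GI-NLS at ZT1 and not well above background in GI-NES, at least 39.7-fold higher, and at least 46.1-fold higher at ZT16 (adjusted p = 8.69e-11 and 1.03e-10). Col lay between them at -3.31 ± 0.94 and -3.53 ± 0.62. A_84_P762010 was 46.9-fold and 43.2-fold lower in GI-NLS (adjusted p = 1.90e-06 and 2.91e-06), at -2.39 ± 0.55 at ZT16 against 3.04 ± 0.04 in GI-NES and 1.26 ± 0.22 in Col. A_84_P761415 was 13.6-fold and 14.7-fold lower in GI-NLS (adjusted p = 1.90e-05 and 1.10e-05). A_84_P20352 was 5.53-fold higher in GI-NLS at ZT1 (adjusted p = 0.00822) and A_84_P18549 4.61-fold higher at ZT16 (adjusted p = 0.0399). In each case only 1 of 3 GI-NES arrays was well above background. Normexp, a fit of only these groups, slide as a random block and the deposited table ended both calls. Quantile normalization also ended the former (adjusted p = 0.0555), and testing all probes (0.0708) and scan day as a random block (0.285) the latter. A fit of only these groups ended the ZT1 call of A_84_P762010 (adjusted p = 0.117). Leaving out GI-NLS ZT1 replicate 1 or 2 ended the former (adjusted p = 0.113 and 0.0511), and leaving out any GI-NLS ZT16 replicate or GI-NES ZT16 replicate 1 or 2 the latter (0.121, 0.369, 0.157, 0.313 and 0.169).

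The evening probe A_84_P17055 was at -0.58 ± 0.35 in GI-NLS and -3.27 ± 0.61 in GI-NES at ZT16, a difference of 2.69 log2 units that was not past the threshold (adjusted p = 1.00). Its arrays did not overlap between the lines, so the missing call does not show equal levels. A_84_P784337 lay in the same order at ZT16, at -0.96 ± 0.37 in GI-NLS and -3.80 ± 0.66 in GI-NES. The genotypes share no slide or day; slide as a random block gave 4 and 5 probes and a fit of only these groups 2 and 3. Without GI-NES ZT16 replicate 2, 12 probes were called at ZT16.

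How far each line returned the ZT16 levels to Col was also measured with probes chosen on 2 replicates and read on the third, a measure devised after the data were seen. With 31, 13 and 21 probes for replicates 1, 2 and 3, GI restored 90.5% ± 2.28 (SD, n = 3) of the gi-2 change, GI-NLS 87.1% ± 10.6 and GI-NES 78.0% ± 4.52. GI-NLS lay above GI-NES in each of the 3 replicates, by 9.10 percentage points on average. The smallest two-sided exact sign-flip p that 3 replicates allow is 0.25, so the order was not established. The lines lay on other slides than Col and gi-2, and GI-NES on other slides than GI-NLS. Slide and line can therefore not be told apart in these shares.

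**Figure D3:**
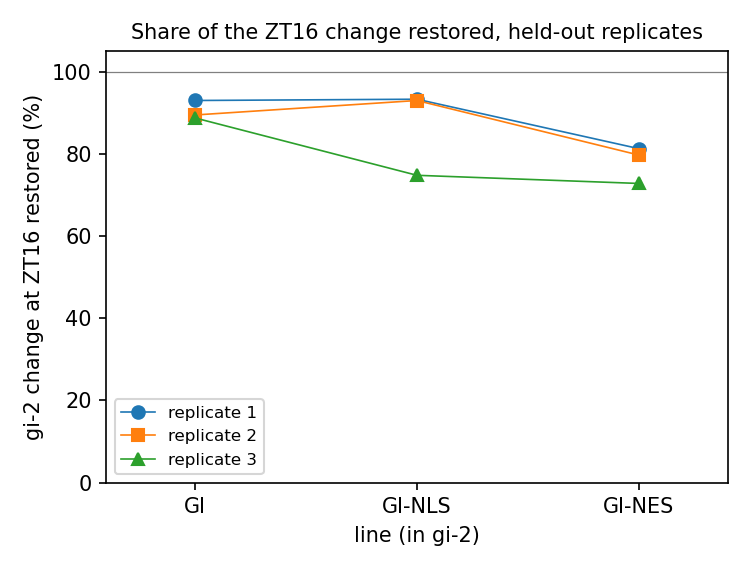
Percent of the gi-2 change at ZT16 restored (vertical axis) in GI, GI-NLS and GI-NES, 1 line per held-out replicate, with 100% at the Col level. GI-NES lies lowest in each replicate, at 81.3%, 79.8% and 72.9%.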

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

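The tests of the array labelled gi-2 ZT1 replicate 3 were chosen only after its place among the arrays was seen, apart from the test of mixed RNA. The counts over other splits of the arrays were planned, except those within slides and without that array.

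The time effect, ZT16 minus ZT1, differed between gi-2 and Col in 42 probes by the test of the difference itself, 37 higher and 5 lower in gi-2. Of 100 splits of the 12 arrays drawn, 1 gave as many, the real one, and the highest of the others gave 39, but these splits ignore that Col and gi-2 arrays shared slides. Of the 32 splits that exchange genotypes only within a slide and time, 2 gave 42 or more, the highest of the others 129. Without the array labelled gi-2 ZT1 replicate 3, 5 of 100 splits gave 33 or more, the highest of the others 333, so chance is not excluded for this count. The count stood at 33 without the array labelled gi-2 ZT1 replicate 3, at 99 with slide as a random block, at 2 with slide as a fixed block and the other genotypes left out, and at 4 with only these groups in the fit. For GI-NLS against GI-NES the time effect differed in 0 probes by limma (149 at an unadjusted p under 0.05), which all 100 splits matched, the highest of the others also giving 0.

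The array labelled gi-2 ZT1 replicate 3 had a time score of 0.897, within the ZT16 arrays (0.887 to 1.06) and above every other ZT1 array (at most 0.141). A slide or day effect is argued against by the Col ZT1 array on the same slide and day, at -0.0625, and a shift of every gi-2 culture at ZT1 by another gi-2 ZT1 array at 0.0305. A mix with a large share of ZT1 RNA would leave ZT16-high probes scoring further ahead of ZT1-high probes than on any ZT16 array, but the difference was 0.116, within the ZT16 range of -0.135 to 0.167. RNA of a ZT16 harvest stays open as a candidate explanation, untested, since the score of 0.897 only restates what was seen. A small share of ZT1 RNA, or 1 culture that was at another phase, stays open too, and the array keeps its label throughout.

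Every comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. Each other split mixes arrays of both groups, so where the groups differ, the difference widens its spread. A low count in the other splits then follows by construction and is no support for the real count. The real count and the highest of the other splits were 109 and 4 for gi-2 against Col at ZT1, 73 and 0 at ZT16, 48 and 1 for GI against gi-2 at ZT1, 62 and 2 at ZT16, 6 and 0 for GI against Col at ZT1, and 7 and 1 at ZT16. They were 8 and 0 for GI-NLS against gi-2 at ZT1, 39 and 1 at ZT16, 16 and 0 for GI-NES against gi-2 at ZT1, and 129 and 1 at ZT16. They were 6 and 0 for GI-NLS against GI at both times, 11 and 0 for GI-NES against GI at ZT1, 16 and 3 at ZT16, and 6 and 0 for GI-NLS against GI-NES at both times. Between the times they were 4435 and 0 in Col, 3071 and 0 in GI-NLS and 3040 and 18 in GI-NES.

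In 2 genotypes another split gave more probes than the harvest times. In gi-2, 4 of the 10 splits gave 2 or more probes, and the highest, 690, set the gi-2 ZT1 replicates 1 and 2 and a ZT16 array against the other 3, the doubtful array among them. In GI, 2 of the 10 splits gave 3621 or more. The highest, 6482, set the 3 dimmest GI arrays (75th percentile of the signal 447 to 541) against the 3 brightest (827 to 1105). It also put both arrays of replicate 1 among the dimmest and both of replicate 2 among the brightest. Signal strength and replicate number can therefore not be told apart in this split. With signal strength as a covariate, 3995 probes differed between the times in GI, and 4531 with slide as a fixed block and the genotypes on other slides left out. Among the 4 splits that part all 3 same-numbered pairs, the highest other count was 137 in gi-2 and 0 in GI.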

How the results depend on the processing

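Tests chosen only after the data were seen were scan day as a random or fixed block, signal strength as a covariate, normexp on the median signal and the replicate block without the array labelled gi-2 ZT1 replicate 3. The others were planned. The direction of every one of the 125 calls of named probes was kept under every alternative run, but not its side of the threshold: normexp lost 38 calls, a fit of only the groups compared 50, the deposited values 17 of 87, slide as a fixed replicate block with the genotypes on other slides left out 9 of 61, slide as a random block 7, quantile normalization 6, no filter 5, scan day as a random block 5, scan day as a fixed block 3 of 17, signal strength 3, the replicate block 2 (A_84_P20352 in GI-NES against GI and A_84_P18549 in GI-NLS against GI-NES, both at ZT16), a 2-fold minimum 0, and leaving out 1 array 59 of 762. A 2-fold minimum, no filter, a fit of only the groups compared, the planned replicate block and the fixed slide block leave log2 differences unchanged. The kept directions there were fixed in advance and are no sign of robustness. The counts were less steady. Signal strength as a covariate moved no count by more than 1.5 times. Fits of only the groups compared use fewer arrays and so have fewer degrees of freedom, and a 2-fold minimum sets a stricter bar by construction. Tests of all probes adjust over more probes, but GI-NLS against GI at ZT1 rose from 6 to 7 with them. Except for the 2-fold minimum, the cause of the changes was not tested. Low signal over background limits the dim probes: 13558 probes were not tested, and folds against groups not well above background are bounds. The largest shift of the median of all probes was 0.06 log2 units (GI against Col at ZT1). Comparisons of the times were not run on the deposited table, whose normalization between the times is not given, and the gene list tests and their alternatives were not run.

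Counts that moved by more than 1.5 times follow, with the reported count in parentheses. An overlap of a line is its count of probes changed in gi-2 against Col and the other way in that line. Normexp gave 23 (48) for GI against gi-2 at ZT1, 3 (6) for GI against Col at ZT1, 4 (7) for GI against Col at ZT16, 4 (8) for GI-NLS against gi-2 at ZT1 and 22 (39) for GI-NLS against gi-2 at ZT16. It also gave 3 (6) for GI-NLS against GI at ZT1, 6 (11) for GI-NES against GI at ZT1, 6 (16) for GI-NES against GI at ZT16, 1 (2) for time in gi-2 and 2 (6) for the GI-NLS overlap at ZT1. Further, it gave 4 (7) for the overlap of both targeted lines at ZT1, 19 (31) for the GI-NLS overlap at ZT16, 25 (39) for the GI-NES overlap at ZT16 and 19 (32) for the overlap of both targeted lines at ZT16. Quantile normalization gave 10 (6) for GI against Col at ZT1 and 1 (2) for time in gi-2. Testing all probes gave 70 (109) for gi-2 against Col at ZT1, 25 (48) for GI against gi-2 at ZT1, 10 (16) for GI-NES against GI at ZT16, 25 (42) for the time effect in gi-2 against Col and 14 (27) for the GI overlap at ZT1. A fit of only the groups compared gave 3 (109) for gi-2 against Col at ZT1, 31 (73) for gi-2 against Col at ZT16, 3 (48) for GI against gi-2 at ZT1, 0 (62) for GI against gi-2 at ZT16 and 1 (6) for GI against Col at ZT1. It also gave 0 (7) for GI against Col at ZT16, 3 (8) for GI-NLS against gi-2 at ZT1, 14 (39) for GI-NLS against gi-2 at ZT16, 3 (16) for GI-NES against gi-2 at ZT1 and 24 (129) for GI-NES against gi-2 at ZT16. Further, it gave 2 (6) for GI-NLS against GI at ZT1, 0 (6) for GI-NLS against GI at ZT16, 2 (11) for GI-NES against GI at ZT1, 1 (16) for GI-NES against GI at ZT16 and 2 (6) for GI-NLS against GI-NES at ZT1. There were 3 (6) for GI-NLS against GI-NES at ZT16, 0 (2) for time in gi-2, 1058 (3621) for time in GI, 4 (42) for the time effect in gi-2 against Col and 2 (27) for the GI overlap at ZT1. There were 1 (6) for the GI-NLS overlap at ZT1, 2 (9) for the GI-NES overlap at ZT1, 1 (7) for the overlap of both targeted lines at ZT1, 0 (45) for the GI overlap at ZT16 and 12 (31) for the GI-NLS overlap at ZT16. There were 15 (39) for the GI-NES overlap at ZT16 and 12 (32) for the overlap of both targeted lines at ZT16. The replicate block gave 376 (109) for gi-2 against Col at ZT1, 125 (73) for gi-2 against Col at ZT16, 341 (48) for GI against gi-2 at ZT1, 1.1e+02, rounded, (62) for GI against gi-2 at ZT16 and 22 (6) for GI against Col at ZT1. It also gave 13 (7) for GI against Col at ZT16, 22 (8) for GI-NLS against gi-2 at ZT1, 71 (39) for GI-NLS against gi-2 at ZT16, 37 (16) for GI-NES against gi-2 at ZT1 and 240 (129) for GI-NES against gi-2 at ZT16. Further, it gave 39 (6) for GI-NLS against GI at ZT1, 7404 (4435) for time in Col, 753 (2) for time in gi-2, 6165 (3621) for time in GI and 5474 (3071) for time in GI-NLS. There were 5615 (3040) for time in GI-NES, 95 (42) for the time effect in gi-2 against Col, 141 (27) for the GI overlap at ZT1, 17 (6) for the GI-NLS overlap at ZT1 and 17 (9) for the GI-NES overlap at ZT1. There were 54 (32) for the overlap of both targeted lines at ZT16. Slide as a fixed replicate block, with the genotypes on other slides left out, gave 21 (109) for gi-2 against Col at ZT1, 38 (73) for gi-2 against Col at ZT16, 3 (6) for GI-NLS against GI at ZT1, 2 (6) for GI-NLS against GI at ZT16 and 7084 (4435) for time in Col. It also gave 0 (2) for time in gi-2 and 2 (42) for the time effect in gi-2 against Col. Slide as a random block gave 518 (109) for gi-2 against Col at ZT1, 122 (73) for gi-2 against Col at ZT16, 28 (48) for GI against gi-2 at ZT1, 47 (129) for GI-NES against gi-2 at ZT16 and 11 (6) for GI-NLS against GI at ZT1. It also gave 7464 (4435) for time in Col, 751 (2) for time in gi-2, 6065 (3621) for time in GI, 5509 (3071) for time in GI-NLS and 5401 (3040) for time in GI-NES. Further, it gave 99 (42) for the time effect in gi-2 against Col. The deposited table gave 20 (109) for gi-2 against Col at ZT1, 9 (48) for GI against gi-2 at ZT1, 4 (8) for GI-NLS against gi-2 at ZT1, 9 (16) for GI-NES against gi-2 at ZT1 and 3 (6) for GI-NLS against GI at ZT1. It also gave 3 (6) for GI-NLS against GI-NES at ZT1, 14 (7) for GI against Col at ZT16, 84 (129) for GI-NES against gi-2 at ZT16, 6 (16) for GI-NES against GI at ZT16 and 5 (27) for the GI overlap at ZT1. Further, it gave 3 (6) for the GI-NLS overlap at ZT1, 5 (9) for the GI-NES overlap at ZT1 and 4 (7) for the overlap of both targeted lines at ZT1. A 2-fold minimum gave 2086 (4435) for time in Col, 1 (2) for time in gi-2, 1864 (3621) for time in GI, 1533 (3071) for time in GI-NLS and 1638 (3040) for time in GI-NES. Scan day as a random block gave 278 (109) for gi-2 against Col at ZT1, 23 (48) for GI against gi-2 at ZT1, 10 (6) for GI-NLS against GI at ZT1, 10 (16) for GI-NES against GI at ZT16 and 234 (2) for time in gi-2. It also gave 15 (27) for the GI overlap at ZT1 and 15 (9) for the GI-NES overlap at ZT1. Scan day as a fixed block gave 160 (16) for GI-NES against gi-2 at ZT1 and 56 (129) for GI-NES against gi-2 at ZT16. The replicate block without the array labelled gi-2 ZT1 replicate 3 gave 26 (16) for GI-NES against gi-2 at ZT1, 4158 (2) for time in gi-2, 80 (42) for the time effect in gi-2 against Col and 10 (6) for the GI-NLS overlap at ZT1. The replicate block moved no other count by more than 1.5 times. Where the numbers do not pair the arrays, 3, 4, 4, 3 and 3 of 6 arrays correlated best with their own number (GI-NES against gi-2 at ZT1 and ZT16, GI-NLS against GI at ZT16, GI-NES against GI at ZT1 and GI-NLS against GI-NES at ZT16), and 33 and 29 of 36 comparisons of arrays did so for the time effects in gi-2 against Col and in GI-NLS against GI-NES. The lowest pair correlation among these was -0.111.

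Leaving out 1 array at a time gave ranges of 39 to 469 (109) for gi-2 against Col at ZT1, 4 to 10 (6) for GI against Col at ZT1, 2777 to 4472 (4435) for time in Col, 15 to 65 (42) for the time effect in gi-2 against Col, 15 to 328 (48) for GI against gi-2 at ZT1 and 6 to 55 (8) for GI-NLS against gi-2 at ZT1. Other ranges were 0 to 2418 (2) for time in gi-2, 10 to 237 (27) for the GI overlap at ZT1, 4 to 44 (6) for the GI-NLS overlap at ZT1, 7 to 18 (9) for the GI-NES overlap at ZT1, 7 to 13 (7) for the overlap of both targeted lines at ZT1 and 5 to 10 (6) for GI-NLS against GI at ZT1. For the rest they were 1739 to 2381 (3071) for time in GI-NLS, 1920 to 2302 (3040) for time in GI-NES, 36 to 50 (73) for gi-2 against Col at ZT16, 37 to 60 (62) for GI against gi-2 at ZT16, 20 to 31 (39) for GI-NLS against gi-2 at ZT16 and 34 to 198 (129) for GI-NES against gi-2 at ZT16. They were 26 to 33 (45) for the GI overlap at ZT16, 14 to 26 (31) for the GI-NLS overlap at ZT16, 18 to 28 (39) for the GI-NES overlap at ZT16, 15 to 25 (32) for the overlap of both targeted lines at ZT16, 5 to 12 (6) for GI-NLS against GI-NES at ZT16 and 9 to 45 (16) for GI-NES against GI at ZT16. The ranges of all overlaps cover only gi-2 arrays left out. Overlaps without an array of Col or of a line were not counted. Among the overlaps, there were for the GI overlap at ZT1 237, 92 and 10 without gi-2 ZT1 replicates 1, 2 and 3, for the GI-NLS overlap at ZT1 44 and 10 without gi-2 ZT1 replicates 1 and 2, for the GI-NES overlap at ZT1 18 without gi-2 ZT1 replicate 1 and for the overlap of both targeted lines at ZT1 13 without gi-2 ZT1 replicate 1. Further, there were for the GI overlap at ZT16 26 and 29 without gi-2 ZT16 replicates 2 and 3, for the GI-NLS overlap at ZT16 14 and 20 without gi-2 ZT16 replicates 2 and 3, for the GI-NES overlap at ZT16 18 and 18 without gi-2 ZT16 replicates 2 and 3 and for the overlap of both targeted lines at ZT16 15 and 15 without gi-2 ZT16 replicates 2 and 3.

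The split of higher and lower calls moved by over 10 percentage points with the scaling in these cases, with the reported split in parentheses. With normexp it was 3 and 1 (5 and 3) for GI-NLS against gi-2 at ZT1, 9 and 3 (9 and 7) for GI-NES against gi-2 at ZT1, 4 and 2 (6 and 5) for GI-NES against GI at ZT1, 4 and 2 (8 and 8) for GI-NES against GI at ZT16, 2 and 2 (4 and 2) for GI-NLS against GI-NES at ZT1 and 1 and 0 (1 and 1) for time in gi-2. With quantile normalization it was 5 and 5 (2 and 4) for GI against Col at ZT1, 4 and 5 (2 and 5) for GI against Col at ZT16, 6 and 1 (4 and 2) for GI-NLS against GI at ZT1, 8 and 4 (6 and 5) for GI-NES against GI at ZT1, 2 and 2 (4 and 2) for GI-NLS against GI-NES at ZT1 and 1 and 0 (1 and 1) for time in gi-2. With the deposited table it was 6 and 14 (78 and 31) for gi-2 against Col at ZT1, 6 and 3 (25 and 23) for GI against gi-2 at ZT1, 3 and 3 (2 and 4) for GI against Col at ZT1, 3 and 1 (5 and 3) for GI-NLS against gi-2 at ZT1, 1 and 2 (4 and 2) for GI-NLS against GI-NES at ZT1 and 59 and 24 (42 and 31) for gi-2 against Col at ZT16. It was also 26 and 36 (34 and 28) for GI against gi-2 at ZT16, 9 and 5 (2 and 5) for GI against Col at ZT16, 44 and 40 (88 and 41) for GI-NES against gi-2 at ZT16, 4 and 1 (4 and 2) for GI-NLS against GI at ZT16 and 4 and 2 (8 and 8) for GI-NES against GI at ZT16.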

Other observations

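The tests of hypotheses and of shared deviations in this part were chosen only after the results were seen, except the fit on signal strength, and the limma tests of single probes were planned.

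A_84_P172991 was higher in the mutant at ZT16 than in Col and in every line with GI. It was at -1.93 ± 0.40 (SD, n = 3) in gi-2 and -4.21 ± 0.21 in Col at ZT16, 4.88-fold higher in the mutant (adjusted p = 0.00542, and 0.0689 without gi-2 ZT16 replicate 2). The probe was not well above background at ZT16 in GI, GI-NLS or GI-NES, at least 10.4-fold, 12.1-fold and 11.6-fold below gi-2 (adjusted p = 4.73e-07, 6.10e-06 and 1.57e-07). A_84_P550153 was at -3.86 ± 0.07 in gi-2 at ZT16 and not well above background in Col, GI-NLS or GI-NES, while GI, at -4.49 ± 1.03 (2 of 3 arrays well above background), did not pass the test against gi-2 (adjusted p = 1.00). It was at least 3.29-fold lower in GI-NLS and 3.05-fold lower in GI-NES than in gi-2 (adjusted p = 2.17e-05 and 8.64e-04), and normexp ended both calls.

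A_84_P762010 had its highest mean at ZT16 in the cytosolic line, which was not tested against Col. It was 7.98-fold lower in gi-2 than in Col at ZT16 (adjusted p = 0.00521, but 0.0588 without gi-2 ZT16 replicate 2 and 0.0596 with slide as a fixed block and only the genotypes on those slides), and 27.4-fold higher in GI-NES than in gi-2 (adjusted p = 1.08e-05), with GI-NES at 3.04 ± 0.04 and Col at 1.26 ± 0.22. GI and GI-NLS were at -0.98 ± 0.76 and -2.39 ± 0.55, beside gi-2 at -1.74 ± 0.65. A_84_P20352 was 3.63-fold lower in GI-NES than in gi-2 at ZT16 (adjusted p = 0.0253), but leaving out any gi-2 ZT16 replicate or GI-NES ZT16 replicate 1 or 3 ended that call (adjusted p = 0.133, 0.0504, 0.131, 0.181 and 0.0765), as did normexp, quantile normalization, a fit of only these groups, slide as a random block, scan day as a fixed block and the deposited table (0.841, 0.0716, 0.140, 0.130, 0.0654 and 0.0790).

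A hypothesis is that in gi-2 at ZT16, probes that normally fall from ZT1 to ZT16 stay higher. Of the 42 probes higher in gi-2 than in Col at ZT16, 32 (76.2%) were higher at ZT1 than at ZT16 in each of GI, GI-NLS and GI-NES, against 3.15% of the tested probes (two-sided Fisher's exact test, p = 5.86e-40, adjusted 2.35e-39 over 4 tests). The arrays of these lines entered the choice of the 42 through the shared estimate of the spread and through the filter on dim probes. Of the 31 lower probes, 5 (16.1%) were of the ZT16-high class, against 3.29% (two-sided Fisher's exact test, p = 0.00319, adjusted 0.00638). Probes are not independent, since several may report 1 gene, so these p-values are too small by an unknown amount. The result is consistent with the hypothesis, which was found and tested on the same arrays.

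A second hypothesis is that nuclear and cytosolic GI restore the ZT16 changes by different shares. GI-NLS exceeded GI-NES by 9.10 percentage points on average over held-out replicates (12.0, 13.3 and 1.99), but 3 replicates cannot give a two-sided exact p under 0.25. Of the 73 probes, 3 went the other way in GI-NLS and not in GI-NES and 11 in GI-NES and not in GI-NLS, which counts calls and does not test a difference. The data leave the order open.

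Arrays of the same replicate number deviated together even on different slides. The median correlation of deviations from the group means was 0.343 over 96 same-numbered pairs on different slides. It was -0.223 over 192 differently numbered pairs, which centring on means of 3 arrays makes negative where same-numbered arrays agree. GI-NES replicates 1 and 2, which shared slide and scan day, correlated at -0.340 and -0.493 across the times, no higher than that median. This argues against slide or scan day as the cause, in this genotype only. Signal strength is argued against by the median of 0.324 for same-numbered pairs after a fit on it. A culture or harvest shared under a number may explain it, which the labels do not state and which stays untested, since the median of 0.343 only restates what was seen. Correlations are across probes, which are not independent.

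Against both Col and gi-2, 3 probes were lower in GI at both times, A_84_P66154, A_84_P17214 and A_84_P818717, the last pair named here after their values were seen. GI-NLS, on the same slides as GI, returned a median of 0.983 of the difference between GI and gi-2 at ZT1 and 1.07 at ZT16, which argues against slide or day. The labels give no second line of any construct, so whether the change belongs to the untargeted construct or to the line was not tested.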
